A study of Homo sapiens with 73 samples.

How the data were processed

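RNA was extracted with the Qiagen AllPrep kit from CHLA-9 cultures, and reads were aligned and counted with STAR, per the labels' protocols. The submitters' processing notes name STAR and featureCounts and the genome build GRCh38, without versions. The deposited table holds a signal, quantile-normalized counts, for 36233 genes in 73 columns, as the deposited values show: treated columns share 1 total and a largest value of 114345, and DMSO and parental columns another total and a largest value of 114407. Above 100, sorted columns differed by up to 3.80% within the treated arm and 1.15% among DMSO and parental columns. How the normalization was done is not stated in the labels. Library depth is unknown, and no counting interval is given.

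The groups came from the labels: 7 treated lineages (49 libraries), 3 DMSO lineages (23 libraries) and 1 parental library. Values were analysed as log2 of the value plus 1 (pseudocount 1) for the 14565 genes with a mean of at least 10, in R 4.3.3 with limma 3.58.1 (trend) and data.table (version 1.17.8). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg).

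Over all time points, each lineage was given a value adjusted for time point by least squares, and the 7 treated and 3 DMSO values were compared. Single time points were compared in a shared fit of 72 libraries with a mean per arm and time point. Changes per time point were least squares slopes within each lineage, tested per arm and between arms. After VDC and after EC were compared in the 49 treated libraries with lineage as a replicate block and a linear time term, and the difference of this effect between arms in 72 libraries. Libraries of the same lineage are repeated samples of 1 culture by the labels. Their deviations correlated at a mean of 0.0814 over 219 pairs, against -0.0152 for other pairs of the arm, and neighbouring time points at 0.231. Distances were root mean square log2 differences, tested by exact permutation over 120 splits.

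The 28 gene lists, with 752 members, were fixed together with the comparisons, the naming rule and most other settings before the data were examined. List tests were planned over all time points, for the slope difference and for the last course. Those on the slopes of each arm were outside that plan. All members were found among the 36233 genes, 13 of them under another symbol. Lists with at least 5 kept genes were tested with limma camera at a preset correlation of 0.01 and with an estimated one. Mitochondrially encoded, ribosomal protein, histone and immediate early genes were included as lists for RNA quality and handling. Epithelial, blood cell, and muscle and fibroblast markers were included as lists for other cell types. The lists reported were EWSR1-FLI1-activated genes, EWSR1-FLI1-repressed genes, drug efflux and uptake transporters, topoisomerases and tubulins, aldehyde, glutathione and anthracycline metabolism, homologous recombination and Fanconi anaemia repair, end joining, excision and crosslink repair, G2/M and mitosis genes, G1/S and replication genes, replication-dependent histone genes, apoptosis regulators of the BCL2 and IAP families, mesenchymal and extracellular matrix genes, neural and neural crest genes, interferon-stimulated genes, antigen presentation genes, NF-kB and secretory inflammatory genes, immediate early genes, ATF4 and unfolded protein response genes, cholesterol biosynthesis genes, hypoxia and glycolysis genes, mitochondrially encoded genes, ribosomal protein genes, epithelial markers, blood cell markers, muscle and fibroblast markers, receptor tyrosine kinases and ligands and targets of agents used in solid tumour drug screens.

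The naming rule covered the comparison over all time points, the slope difference and the last course: genes past the threshold whose lineages all lay on 1 side, the 10 largest in each direction, or, where none passed, the 5 smallest p-values in each direction. At time points 1 and 8 it took the 3 largest past the threshold in each direction. From each list it took up to 4 members past the threshold with the largest differences, or else the 2 with the smallest p-values, and always EWSR1, FLI1, TOP2A, ABCB1, SLFN11, CDKN1A, MDM2, MKI67 and NR0B1 where kept. The same rule without list members was applied to the slopes of each arm and to time points 9 and 10 after the data were seen. Genes without a symbol were left out. 5 further genes and 1 list chosen by these rules entered every fit and count but are not reported here.

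The functions were tested on simulated data with the real gene means and spreads and 200 changed genes among 14565. A log2 difference of 1 over all time points was recovered for 89.7% of changed genes, at time point 8 for 61.3%, at time point 9 for 55.2% and after VDC for 91.8%. A change adding 1 log2 unit over 9 time points was recovered for 57.5% in treated slopes and for 0% in the slope difference, where 2 units were recovered for 63.0%. Unchanged simulated data gave 0 calls. The simulated noise was independent between genes, with lineage offsets but without lineage slopes or outlying libraries. These recovery shares and the 0 calls hold for that setting only. Alternatives changed the pseudocount, filter, scaling, limma settings, lineage block, time terms and time points, and left out each lineage in turn. Further alternatives, chosen after seeing the data, left out 9 libraries in groups (4 late DMSO libraries, R9 at time points 8 and 9 and R10 at time points 9 and 10, 2 late treated libraries, R1 at time point 9 and R2 at time point 10, R8 at time point 1 with R1 at time point 3, and R7 at time point 6), or added the number of genes at the lowest value as a covariate. The parental library entered only the distances. Gene positions came from GENCODE v29. No drug response measurements were used.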

Results

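CHLA-9 is an established Ewing sarcoma cell line that carries the EWSR1-FLI1 fusion. Total RNA was sequenced from 73 libraries of an evolution experiment in culture: 7 lineages (R1 to R7) exposed in turn to VDC (vincristine, doxorubicin and cyclophosphamide) and EC (etoposide and cyclophosphamide), 3 lineages (R8 to R10) kept with the solvent DMSO, and the untreated parental line. Each exposure lasted 5 days at the concentration giving 70% effect and was followed by regrowth without drug to near confluency, when RNA was taken. Odd time points followed VDC and even ones EC, over 10 time points or 5 cycles. The treated lineages gave 49 libraries, the DMSO lineages 23 and the parental line 1. At time point 2 only DMSO lineages were sequenced and at time point 3 only treated ones.

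The deposited values were quantile-normalized counts of 36233 genes, so the depth of each library is unknown. Every treated column summed to 13583520 and every DMSO or parental column to 13582508. Between 13214 and 16107 genes per library lay at its lowest value. Of the genes, 14565 had a mean of at least 10 and were tested. The lineage was the unit of replication over all time points, for slopes and for distances. At single time points the spread came from 72 libraries without a lineage term. The last course was tested on libraries with lineage as a block.

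The first question was how far the cultures moved from the parental line, and whether drugs moved them further. The root mean square log2 difference from the parental library was 0.686 ± 0.0787 (SD, n = 6 libraries) in treated lineages at time point 1 and 1.07 ± 0.285 (SD, n = 3) at time point 10. In DMSO lineages it was 0.748 ± 0.0299 (SD, n = 3) at time point 1 and 1.04 ± 0.213 (SD, n = 3) at time point 9, but 0.664 at time point 4 and 0.725 at time point 5. Single libraries weighed on the late means: without R2 the treated mean at time point 10 was 0.902, and without R9 the DMSO mean at time point 9 was 0.913. Averaged per lineage, it was 0.839 ± 0.0337 (SD, n = 7) in treated and 0.850 ± 0.0282 (SD, n = 3) in DMSO lineages, and the difference of -0.0108 did not pass an exact permutation test (2-sided p = 0.633, 120 splits). These averages were not adjusted for time point, and lineages were sampled at different time points, so the sign may reflect sampling. Within time points, the treated mean was higher at 4, 5, 6 and 10 and lower at 1, 7, 8 and 9. Lineages of the same arm lay 0.601 apart under treatment and 0.712 apart in DMSO at the same time point (difference -0.111, exact permutation p = 0.383, 2-sided). Both differences changed sign without 4 late DMSO libraries, to 0.0659 and 0.00321.

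**Figure D1:**
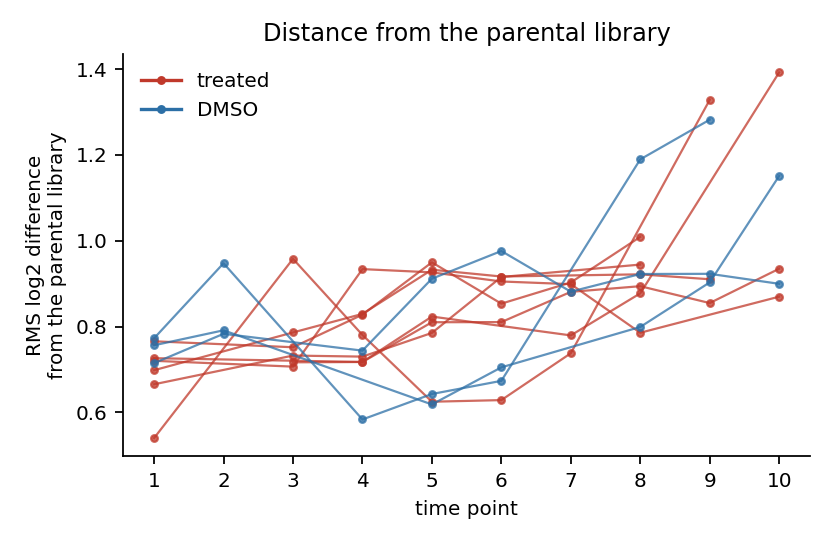
Root mean square log2 difference from the parental library (y axis) over 14565 genes at each time point (x axis). Each point is a library and each line a lineage, treated in red and DMSO in blue. Treated lineages averaged 0.686 at time point 1 and 1.07 at time point 10.

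The second question was whether repeated chemotherapy left an expression difference between treated and DMSO lineages over all time points. No gene passed. MKX and TTLL7, the transcription factor and tubulin-modifying enzyme with the smallest p-values, lay higher in treated lineages, and the nuclear receptor NR0B1, an EWSR1-FLI1 target, lay lower. All 7 treated lineages lay beyond all 3 DMSO lineages for each of these genes. With limma with Benjamini-Hochberg adjustment, 0 of 14565 genes passed, the smallest adjusted p was 0.138, and 1968 genes had an unadjusted p under 0.05. The 5 smallest p-values among higher genes belonged to MKX (0.96 ± 0.13, SE, log2), TTLL7 (1.81 ± 0.26), ARHGAP42 (1.14), INHBA (1.20) and PAM (1.498). Among lower genes they belonged to ITM2A (-0.29), ITGB2 (-0.75), TSR1 (-0.18), CAMK1G (-0.43) and UNC13A (-1.27). MKX lies on chromosome 10 from 27672875 to 27746060 and UNC13A on chromosome 19 from 17601328 to 17688365 (GRCh38, GENCODE v29). NR0B1 differed by -0.38 ± 0.083 (SE, log2, adjusted p = 0.255 in limma with Benjamini-Hochberg). Without DMSO lineage R8, 1357 genes passed.

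Among the gene lists reported, matrix genes, EWSR1-FLI1-repressed genes and mitosis genes ranked higher in treated lineages, whereas ribosomal protein, cholesterol and histone genes ranked lower, all at a preset correlation only. None held with limma camera at an estimated correlation, where each had adjusted p = 0.719 with an estimated correlation (Benjamini-Hochberg). With limma camera at a preset correlation and Benjamini-Hochberg adjustment over the lists, 9 of 27 lists passed, 5 upward and 4 downward. The upward lists were mesenchymal and extracellular matrix genes (median log2 0.23, adjusted p = 3.16e-07), G1/S and replication genes (0.079, 0.00407), muscle and fibroblast markers (0.59, 0.00407), G2/M and mitosis genes (0.057, 0.0102) and EWSR1-FLI1-repressed genes (0.13, 0.0422). The downward lists included ribosomal protein genes (median log2 -0.10, adjusted p = 5.16e-11), cholesterol biosynthesis genes (-0.16, 8.56e-06) and replication-dependent histone genes (-0.14, 0.000177). Ribosomal protein and histone genes are lists for RNA quality and handling. Over time points 1 to 7 only, the mean of the G1/S list turned to -0.0021. No member passed over all genes. Adjusted over the list alone, 6 of 29 mesenchymal and extracellular matrix genes were higher, as were 2 of 21 EWSR1-FLI1-repressed genes and 1 of 18 neural and neural crest genes. Of 30 EWSR1-FLI1-activated genes, 2 were higher and 1 lower.

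The members of each list with the smallest p-values over all time points, none past the threshold, covered collagens, receptors and repair enzymes. Smallest p-values (log2 difference in brackets) belonged to NR0B1 (-0.38) and PAPPA (0.43) of the EWSR1-FLI1-activated genes, NNMT (0.73) and COL1A2 (0.35) of the EWSR1-FLI1-repressed genes, SLC22A4 (0.33) and ABCA3 (0.17) of the drug efflux and uptake transporters, and MAPT (-0.18) and TUBA4A (0.46) of the topoisomerases and tubulins. The next lists gave GPX1 (-0.19) and AKR1C3 (0.34) of the aldehyde, glutathione and anthracycline metabolism, SLFN11 (-0.14) and MRE11 (0.12) of the homologous recombination and Fanconi anaemia repair, OGG1 (-0.13) and LIG4 (-0.18) of the end joining, excision and crosslink repair, and CENPF (0.12) and CCNB1 (0.11) of the G2/M and mitosis genes. They were followed by CCNE1 (0.26) and POLA1 (0.10) of the G1/S and replication genes, H2AC6 (-0.21) and H2BC5 (-0.10) of the replication-dependent histone genes, BMF (-0.16) and BCL2L11 (0.32) of the apoptosis regulators of the BCL2 and IAP families, and COL5A1 (0.41) and POSTN (2.65) of the mesenchymal and extracellular matrix genes. Members of the following lists were NCAM1 (1.83) of the neural and neural crest genes, IFI6 (0.62) and OAS1 (-0.25) of the interferon-stimulated genes, CD274 (0.78) and HLA-C (0.19) of the antigen presentation genes, and PLAU (1.01) and CXCL8 (-0.87) of the NF-kB and secretory inflammatory genes. Others were DUSP2 (-0.86) and NR4A3 (0.45) of the immediate early genes, CEBPB (-0.20) and SLC7A5 (0.20) of the ATF4 and unfolded protein response genes, HSD17B7 (-0.33) and FDFT1 (-0.25) of the cholesterol biosynthesis genes, and PFKFB3 (0.21) and P4HA2 (0.87) of the hypoxia and glycolysis genes. In further lists the members were ND1 (0.11) and CYTB (0.060) of the mitochondrially encoded genes, RPS19 (-0.12) of the ribosomal protein genes, ESRP1 (0.66) and KRT17 (-0.55) of the epithelial markers, and CD79A (-0.45) and CORO1A (-0.29) of the blood cell markers. The last lists gave COL3A1 (0.59) and COL1A1 (0.83) of the muscle and fibroblast markers, IGF1R (-0.17) and FGFR1 (0.19) of the receptor tyrosine kinases and ligands, and SLFN11 (-0.14) and BCL2L1 (-0.16) of the targets of agents used in solid tumour drug screens.

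Treated and DMSO libraries were next compared at single time points, which asks when a difference appeared. At time point 9, CACNB4 (3.84 log2), ARHGAP42 (3.01) and TMEM132B (2.95) were higher in treated libraries, and CTNND2 (-7.10), NPR3 (-6.93) and BLACAT1 (-6.70) were lower. The latter 3 belong to genes chosen for high levels in late R9 libraries, and only R9 and R10 carried their difference at time point 9: R8, R9 and R10 had 1.15, 3542 and 1395 for CTNND2, 13.5, 4156 and 1609 for NPR3 and 2.48, 1100 and 494 for BLACAT1. None of these 6 genes passed without lineage R1 or without R9. At time point 10, SLC12A8 (3.14), PTN (2.80) and BOC (2.66) were higher and CES1 (-4.10), ITGB2 (-2.83) and CYP3A5 (-1.47) lower. That comparison rested on only 2 DMSO libraries, of R8 and R10. With limma with Benjamini-Hochberg adjustment, 194 genes passed at time point 9 (79 higher, 115 lower) and 9 at time point 10 (5 higher, 4 lower). Counts of 0 were found with limma and Benjamini-Hochberg at time points 1, 4, 5, 6 and 8, where 376, 450, 197, 568 and 1475 genes had an unadjusted p under 0.05. Other choices gave calls there: 519 genes passed at time point 8 without lineage R8, and at time point 1 20 passed without R8 at time point 1 and R1 at time point 3 and 292 without 9 libraries. With array weights, whose fit stopped before full convergence, 5262, 116 and 3809 passed at time points 1, 4 and 6. Without 4 late DMSO libraries the limma counts at time points 9 and 10 were 0 (784 and 1434 genes at an unadjusted p under 0.05). That leaves R8 as the lone DMSO library at both time points, assumed to vary like the other groups, so these counts say little about stability. In a separate limma fit per time point the counts were 0 as well (513 and 336). CTNND2 lies on chromosome 5 from 10971840 to 11904043 and NPR3 on chromosome 5 from 32689070 to 32791724 (GRCh38).

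The change per time point within each lineage asks what moved over the 5 cycles. In treated lineages the membrane scaffold gene EPB41L3, the adhesion gene L1CAM and the tenascin gene TNC rose, with a positive slope in each of the 7 lineages. MYCN fell in all 7, and so did SLFN11. All 13 mitochondrially encoded genes, a list for RNA quality and handling, fell. With limma with Benjamini-Hochberg adjustment, 5741 genes passed, 2274 rising and 3467 falling, at a median absolute change of 0.0813 log2 per time point. The 10 with the largest rise per time point were EPB41L3 (0.81), GPRC5A (0.70), L1CAM (0.70), TFPI2 (0.68), PAM (0.66), MXRA5 (0.65), NALF1 (0.65), TNC (0.64), CREB5 (0.64) and SGMS2 (0.63). EPB41L3 and GPRC5A belong to 44 genes chosen for high levels in R1 at time point 9 and R2 at time point 10, where EPB41L3 had 5113 and 7685 against a median of 6.60 elsewhere. Without these 2 libraries EPB41L3 (0.65) and GPRC5A (0.57) still passed in limma and L1CAM (0.68) did not. The 10 with the largest fall were LNCTAM34A (-0.35), FGD5 (-0.32), RN7SL399P (-0.30), IL16 (-0.30), ART3 (-0.29), TRABD2A (-0.29), NOXA1 (-0.28), CFAP161 (-0.28), DPY19L2P1 (-0.28) and MYCN (-0.27). SLFN11 changed by -0.047 ± 0.011 (SE, adjusted p = 0.00856 in limma with Benjamini-Hochberg). FLI1 (0.0084), EWSR1 (0.0057), TOP2A (-0.021), MKI67 (-0.027), MDM2 (-0.023), NR0B1 (-0.037) and CDKN1A (0.010) did not pass. Without time point 1, 426 genes passed.

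Of the lists, EWSR1-FLI1-repressed genes ranked upward in treated lineages at a preset correlation of limma camera but not with an estimated one (Benjamini-Hochberg adjusted p = 0.269 with an estimated correlation). Of its 21 members, 15 rose past the threshold and none fell (17 adjusted over the list alone). The median slope of the list was negative in treated lineage R5 (-0.049) and positive in the other 6 treated lineages and in R8, R9 and R10 (0.088, 0.12 and 0.13). R5 had no library at time point 1, so its slope began at time point 3. Mesenchymal and extracellular matrix genes followed with 19 of 29 (20 adjusted over the list alone), antigen presentation genes with 11 of 16 (13) and ATF4 and unfolded protein response genes with 16 rising and 1 falling of 27 (17 and 1). Of 33 homologous recombination and Fanconi anaemia genes 16 fell (17 adjusted over the list alone), and of 33 end joining, excision and crosslink repair genes 10 fell and 2 rose (10 and 2). With limma camera and Benjamini-Hochberg, 16 of 27 lists passed, 12 upward and 4 downward, with adjusted p = 1.21e-06 for the repressed genes, 8.83e-07 for the ATF4 list, 1.09e-06 for ribosomal protein genes, 1.11e-06 for matrix genes and 3.72e-06 for mitochondrial, antigen presentation and immediate early genes alike. Hypoxia and glycolysis genes (0.000212), receptor tyrosine kinases and ligands (0.00227), BCL2 and IAP family genes (0.0191), NF-kB and secretory genes (0.0212), aldehyde and glutathione genes (0.0262) and muscle and fibroblast markers (0.0374) also ranked upward. Homologous recombination (5.4e-05), cholesterol biosynthesis (0.00598) and end joining genes (0.0235) ranked downward. All 16 were lost with limma camera at an estimated correlation (Benjamini-Hochberg), with adjusted p = 0.127 with an estimated correlation for antigen presentation, 0.365 for aldehyde and glutathione, 0.415 for ribosomal protein, 0.558 for cholesterol and 0.269 for each of the other lists.

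DMSO lineages, grown without drug, changed as well. The natriuretic peptide receptor NPR3 and the catenin gene CTNND2 rose, mostly in R9 and R10, and the transporter gene SLC12A8 fell. All 13 mitochondrially encoded genes fell here too, and 13 of 27 ATF4 and unfolded protein response genes rose (20 rising and 1 falling adjusted over the list alone). With limma with Benjamini-Hochberg adjustment, 1437 genes passed, 663 rising and 774 falling. The 10 with the largest rise per time point were NPR3 (1.12), CTNND2 (1.00), NOS1 (0.98), IGSF10 (0.91), ANGPTL2 (0.90), FEV (0.87), PIK3CG (0.85), BLACAT1 (0.84), RUBCNL (0.81) and VGF (0.80). Of these, NPR3, CTNND2, IGSF10, FEV, BLACAT1 and RUBCNL belong to 47 genes chosen for high levels in R9 at time points 8 and 9, and also high in R10 at time points 9 and 10. In R8, CTNND2 had 0.96, 1.15 and 0 at time points 8 to 10, near the floor. Its slope was 0.041 in R8, 1.66 in R9 and 1.29 in R10, and that of NPR3 0.38, 1.75 and 1.23. Without these 4 libraries the slopes of NPR3 and CTNND2 were 0.67 and 0.56 and passed in limma. The 10 with the largest fall were SLC12A8 (-0.41), LINC01122 (-0.36), ABCG1 (-0.34), PLEKHG4B (-0.31), RIMS1 (-0.31), XK (-0.31), TBX5-AS1 (-0.30), GRIN2A (-0.30), TLR6 (-0.29) and ANKRD30BP1 (-0.29). CDKN1A (0.58, adjusted p = 0.0527 in limma with Benjamini-Hochberg) and MDM2 (0.068, adjusted p = 0.0549) just missed the threshold. EWSR1 (0.024), FLI1 (0.012), TOP2A (0.058), SLFN11 (0.0043), MKI67 (0.061) and NR0B1 (0.057) did not pass. Without 4 late DMSO libraries SLFN11 fell past the threshold in DMSO lineages as well (-0.060), as it did without 9 libraries (-0.068), and CDKN1A rose past it (0.53), while NR0B1 turned to -0.017. Without 9 libraries TOP2A (0.12) and MKI67 (0.17) passed too. Without time point 1 no gene passed in limma, where 2837 had an unadjusted p under 0.05, and without lineage R9 none did (2173). Of the lists, 13 of 27 passed limma camera with Benjamini-Hochberg at a preset correlation, 12 upward and 1 downward, and none held with an estimated one. In several, R9 or R9 and R10 moved most: median slopes in R8, R9 and R10 were 0.0057, 0.20 and 0.035 for G2/M genes, -0.0059, 0.35 and 0.33 for epithelial markers and -0.046, 0.19 and 0.097 for immediate early genes. Among them, ATF4 genes had adjusted p = 1.05e-11, mitochondrial genes 1.48e-09, G2/M genes 7.8e-07, antigen presentation genes 3.25e-05, NF-kB genes 0.00176, EWSR1-FLI1-repressed and immediate early genes 0.00388, epithelial markers 0.00677, interferon-stimulated genes 0.015, BCL2 and IAP genes 0.0238, hypoxia genes 0.0361 and receptor tyrosine kinases 0.0453. None held in limma camera with Benjamini-Hochberg when the correlation was estimated: adjusted p = 0.146 with an estimated correlation for ATF4, antigen presentation, BCL2 and epithelial genes, 0.268 for mitochondrial and NF-kB genes, 0.429 for interferon-stimulated genes, 0.448 for receptor tyrosine kinases, and 0.539 for the other lists.

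The slopes of both arms resembled each other. Across genes, which are not independent replicates, Pearson's r between treated and DMSO slopes was 0.751, and 77.6% of genes had the same sign. Of the 1437 genes that passed in DMSO lineages, 1385 had the same sign in treated ones. Genes past the threshold in both arms numbered 1038: 440 rose in both, 590 fell in both and 8 moved apart. Independent lists would share 104 rising and 184 falling genes. Both arms were tested with a shared spread per gene, so their calls are not independent and that comparison is only rough.

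**Figure D2:**
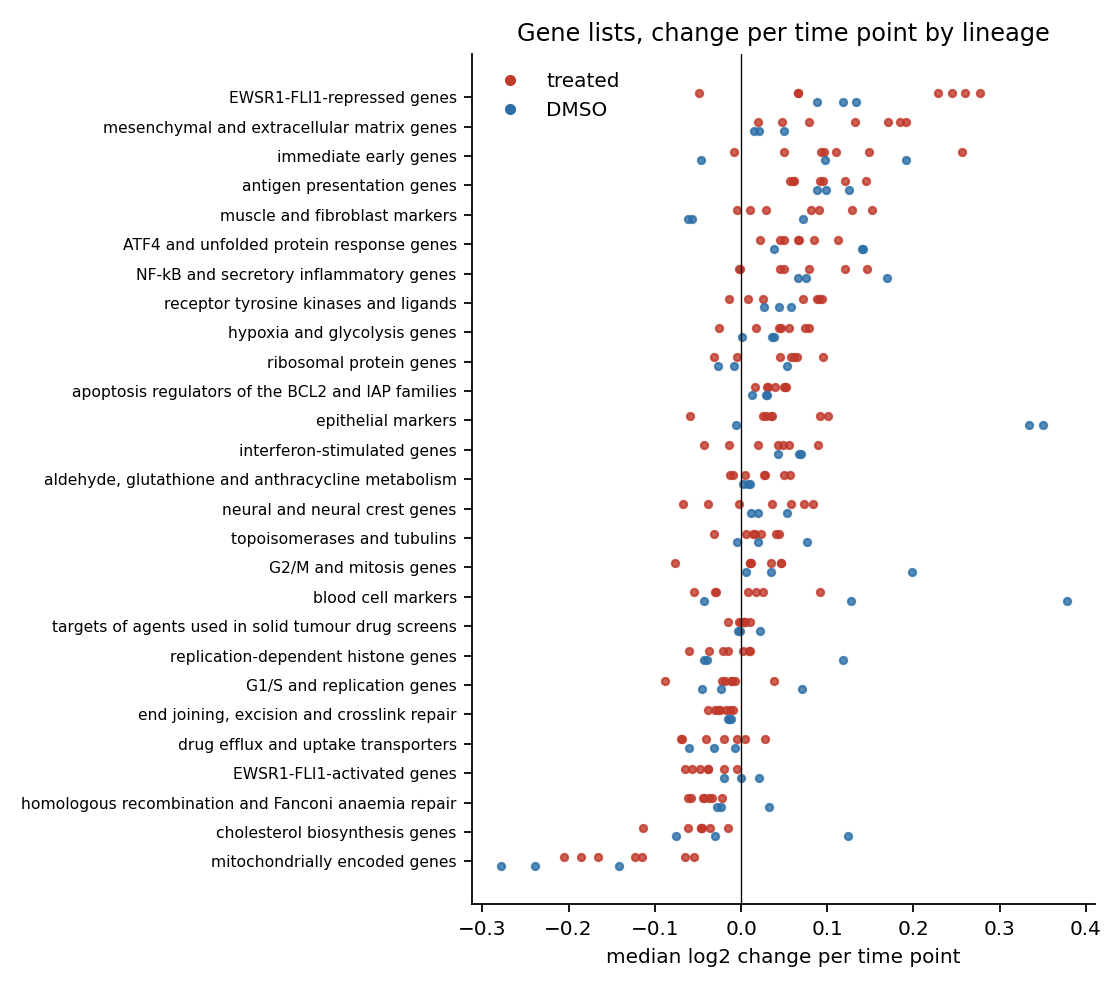
Median log2 change per time point (x axis) of the members of each gene list (y axis). Each point is a lineage, 7 treated in red and 3 DMSO in blue. Mitochondrially encoded genes lie below 0 in all 10 lineages.

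Whether drug exposure altered the slopes was tested as the treated minus DMSO change per time point. No gene passed. The collagen gene COL3A1 tended upward in treated relative to DMSO lineages, and the damage response genes CDKN1A and MDM2 tended downward. With limma with Benjamini-Hochberg adjustment, 0 genes passed, the smallest adjusted p was 0.476, and 1332 had an unadjusted p under 0.05. In a 1-stage fit with a replicate block 321 genes passed (120 higher, 201 lower), without that block 83, and without lineage R8 158. The smallest p-values belonged to LINC01315 (0.22), MIR3609 (0.15), NDST3 (0.21), SCARNA21 (0.17) and RNU6ATAC (0.23) among higher slopes and STRIP2 (-0.13), ZNF467 (-0.11), SOCS2-AS1 (-0.19), CBX6 (-0.092) and GPR37L1 (-0.16) among lower ones. CDKN1A differed by -0.57 ± 0.20 (SE), MDM2 by -0.091 ± 0.024, SLFN11 by -0.051, TOP2A by -0.079, MKI67 by -0.088, NR0B1 by -0.094, EWSR1 by -0.019 and FLI1 by -0.0037. Some signs turned: SLFN11 to 0.013 without 4 late DMSO libraries, NR0B1 to 0.022 without 6 late libraries and 0.028 without 9 libraries, and CBX6 (0.0039), GPR37L1 (0.035) and FLI1 (0.0037) over time points 1 to 7 only. With limma camera and Benjamini-Hochberg, 11 of 27 lists passed at a preset correlation, 4 upward and 7 downward, and none held with an estimated one. Downward lists included G2/M genes (adjusted p = 1.01e-07), homologous recombination and cholesterol genes (each 7.04e-05), ATF4 genes (0.000254), histone genes (0.0186) and EWSR1-FLI1-activated genes (0.0249). Upward were ribosomal protein genes (7.04e-05), mitochondrial genes (0.000128), matrix genes (0.000254) and muscle and fibroblast markers (0.0484). The mean of the ATF4 list turned to 0.046 without 4 late DMSO libraries, 0.020 without 6 late libraries, 0.022 without 9 libraries and 0.034 over time points 1 to 7 only, where the EWSR1-FLI1-activated (0.0045) and matrix lists (-0.017) turned as well. All 11 were lost in limma camera with Benjamini-Hochberg: adjusted p = 0.514 with an estimated correlation for cholesterol, 0.650 for ribosomal protein, 0.730 for histone and 0.508 for each other list.

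For the slope difference, the members of each list with the smallest p-values (log2 per time point in brackets), none past the threshold over all genes, included COL3A1 and NNMT. These were PRKCB (-0.053) and NKX2-2 (-0.19) of the EWSR1-FLI1-activated genes, COL1A2 (0.12) and NNMT (0.30) of the EWSR1-FLI1-repressed genes, ABCB10 (-0.098) and ABCC4 (0.064) of the drug efflux and uptake transporters, and STMN1 (0.053) and TUBA1A (0.19) of the topoisomerases and tubulins. Next came SLC7A11 (-0.13) and HMOX1 (-0.17) of the aldehyde, glutathione and anthracycline metabolism, FANCE (-0.048) and CHEK2 (-0.070) of the homologous recombination and Fanconi anaemia repair, DCLRE1C (-0.077) and OGG1 (-0.069) of the end joining, excision and crosslink repair, and AURKA (-0.11) and BUB1B (-0.073) of the G2/M and mitosis genes. They were followed by MCM7 (-0.044) and RRM1 (-0.067) of the G1/S and replication genes, H2BC17 (-0.11) and H2BC5 (-0.051) of the replication-dependent histone genes, BAX (-0.13) and BCL2L11 (0.093) of the apoptosis regulators of the BCL2 and IAP families, and COL3A1 (0.29) and COL1A2 (0.12) of the mesenchymal and extracellular matrix genes. Other pairs were NGFR (-0.12) of the neural and neural crest genes, USP18 (-0.063) and IFITM2 (-0.13) of the interferon-stimulated genes, TAP2 (-0.039) and TAPBP (-0.036) of the antigen presentation genes, and ICAM1 (-0.46) and CXCL8 (-0.42) of the NF-kB and secretory inflammatory genes. Further pairs were NR4A3 (0.13) and FOS (0.22) of the immediate early genes, SLC7A11 (-0.13) and SESN2 (-0.11) of the ATF4 and unfolded protein response genes, INSIG1 (-0.098) of the cholesterol biosynthesis genes, and PFKFB3 (0.074) and SLC2A1 (0.063) of the hypoxia and glycolysis genes. To these were added ND3 (0.10) and ND2 (0.12) of the mitochondrially encoded genes, RPL27 (0.11) and RPL18 (0.054) of the ribosomal protein genes, ESRP2 (-0.19) and KRT17 (-0.37) of the epithelial markers, and CORO1A (-0.14) and CD79A (-0.16) of the blood cell markers. Last came COL3A1 (0.29) and PAX7 (-0.12) of the muscle and fibroblast markers, AXL (0.076) and EPHA2 (-0.35) of the receptor tyrosine kinases and ligands, and SLFN11 (-0.051) and AURKA (-0.11) of the targets of agents used in solid tumour drug screens.

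The last course received asks whether VDC and EC left different marks. No gene passed. LENG9 and SLC24A3 tended higher after VDC in all 7 treated lineages, and the ligand gene WNT4 and the Frizzled receptor gene FZD4 tended higher after EC. Immediate early and ribosomal protein genes, both lists for RNA quality and handling, ranked higher after VDC at a preset correlation only. EWSR1-FLI1-repressed genes, among them IGFBP3 and CALD1, ranked higher after EC, also at a preset correlation only. None of these list calls held with limma camera at an estimated correlation, where the smallest Benjamini-Hochberg adjusted p = 0.828 with an estimated correlation. With lineage as a replicate block, limma with Benjamini-Hochberg adjustment gave 0 genes, a smallest adjusted p of 0.0511 and 2118 genes at an unadjusted p under 0.05. That count depended on single libraries and lineages: 41 genes passed without R7 at time point 6, 50 without 2 late treated libraries, 164 without lineage R1 and 317 without 9 libraries. The smallest p-values belonged to LENG9 (0.39), SLC24A3 (0.40), TRAPPC9 (0.32), KCNF1 (0.92) and SIX5 (0.32) and, lower after VDC, LINC02593 (-0.58), WNT4 (-0.60), PTPRK (-0.31), FZD4 (-0.49) and TUB (-0.28). EWSR1 (-0.037), FLI1 (0.017), TOP2A (-0.12), MKI67 (-0.15), SLFN11 (0.020), CDKN1A (-0.21), MDM2 (-0.11) and NR0B1 (0.27) did not pass. The VDC minus EC difference did not pass for any gene when treated were set against DMSO lineages (limma, 685 genes at an unadjusted p under 0.05). With limma camera and Benjamini-Hochberg, 9 of 27 lists passed, 3 upward and 6 downward: ribosomal protein genes (adjusted p = 9.23e-07), immediate early genes (0.000137) and histone genes (0.00331) were higher after VDC, and EWSR1-FLI1-repressed genes (5.18e-06), G2/M genes (6.39e-05), matrix genes (0.000926), hypoxia genes (0.0194), homologous recombination genes (0.0218) and G1/S genes (0.026) were lower. The 3 lists higher after VDC were all lists for RNA quality and handling. All 9 were lost in limma camera with Benjamini-Hochberg: adjusted p = 0.840 with an estimated correlation for histone, homologous recombination and G1/S genes and 0.828 for each other list. Adjusted over the list alone, 4 of 21 EWSR1-FLI1-repressed genes were lower after VDC, and none passed over all genes.

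After VDC against after EC, the members of each list with the smallest p-values (log2 difference in brackets), none past the threshold over all genes, included IGFBP3 and AKR1C3. The pairs were JAKMIP2 (0.24) and CAV1 (-1.004) of the EWSR1-FLI1-activated genes, IGFBP3 (-1.03) and CALD1 (-0.44) of the EWSR1-FLI1-repressed genes, SLC22A16 (1.66) and ABCA3 (0.62) of the drug efflux and uptake transporters, and MAP4 (-0.25) and MAPT (0.14) of the topoisomerases and tubulins. Then followed AKR1C3 (-0.40) and GPX3 (-1.36) of the aldehyde, glutathione and anthracycline metabolism, BARD1 (-0.17) and ATR (-0.12) of the homologous recombination and Fanconi anaemia repair, LIG3 (0.20) and ERCC4 (-0.13) of the end joining, excision and crosslink repair, and AURKA (-0.34) and CDK1 (-0.22) of the G2/M and mitosis genes. After these came CCNE2 (-0.33) and RFC3 (-0.17) of the G1/S and replication genes, H2AC6 (0.31) and H1-3 (0.44) of the replication-dependent histone genes, APAF1 (-0.14) and BOK (-0.71) of the apoptosis regulators of the BCL2 and IAP families, and MMP2 (-0.41) and MMP14 (0.31) of the mesenchymal and extracellular matrix genes. Another group of lists gave NEFM (1.03) and UCHL1 (-0.45) of the neural and neural crest genes, USP18 (0.21) and OAS1 (0.22) of the interferon-stimulated genes, TAP1 (0.23) and CIITA (-0.46) of the antigen presentation genes, and TNFAIP3 (0.56) and NFKB2 (0.19) of the NF-kB and secretory inflammatory genes. The lists after that gave NR4A3 (0.37) and JUND (0.28) of the immediate early genes, SLC7A5 (-0.31) and ATF5 (-0.43) of the ATF4 and unfolded protein response genes, TM7SF2 (0.56) and SC5D (-0.26) of the cholesterol biosynthesis genes, and LOX (-0.40) and ENO1 (-0.30) of the hypoxia and glycolysis genes. Beyond these were ND3 (0.27) and ND4L (0.16) of the mitochondrially encoded genes, RPL3 (0.19) and RPS9 (0.19) of the ribosomal protein genes, KRT18 (-1.05) and ESRP1 (-0.70) of the epithelial markers, and CD79A (0.045) of the blood cell markers. Final pairs were MYH3 (-0.44) and PAX7 (0.30) of the muscle and fibroblast markers, IGFBP3 (-1.03) and IRS2 (0.21) of the receptor tyrosine kinases and ligands, and AURKA (-0.34) and ATR (-0.12) of the targets of agents used in solid tumour drug screens.

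Drug transporters, drug targets and neural genes gave no list call. With limma camera and Benjamini-Hochberg over all time points, adjusted p was 0.411 for drug efflux and uptake transporters, 0.269 for topoisomerases and tubulins, 0.16 for neural and neural crest genes and 0.133 for targets of agents in drug screens. The 3 kept blood cell markers were too few to test. ABCB1, the efflux pump gene, fell under the mean of 10 and was not tested: its highest value was 268 in R5 at time point 10. Per arm, mean normalized counts of EWSR1 were 2657 ± 236 (SD, n = 49 libraries) in treated and 2586 ± 250 (SD, n = 23) in DMSO libraries, and those of FLI1 were 1093 ± 99.6 and 1093 ± 107. Over all time points, limma log2 differences were 0.033 for EWSR1, -0.025 for FLI1, 0.051 for TOP2A, 0.022 for MKI67, -0.14 for SLFN11, -0.13 for MDM2 and -0.26 for CDKN1A, and none of these passed. CDKN1A turned to 0.50 without 4 late DMSO libraries. Median, mean and camera direction differed in sign for aldehyde and glutathione genes and hypoxia genes over all time points, for drug transporters and topoisomerases in the slope difference, for muscle markers and histone genes in DMSO slopes, and for drug transporters and cholesterol genes for the last course.

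**Figure D3:**
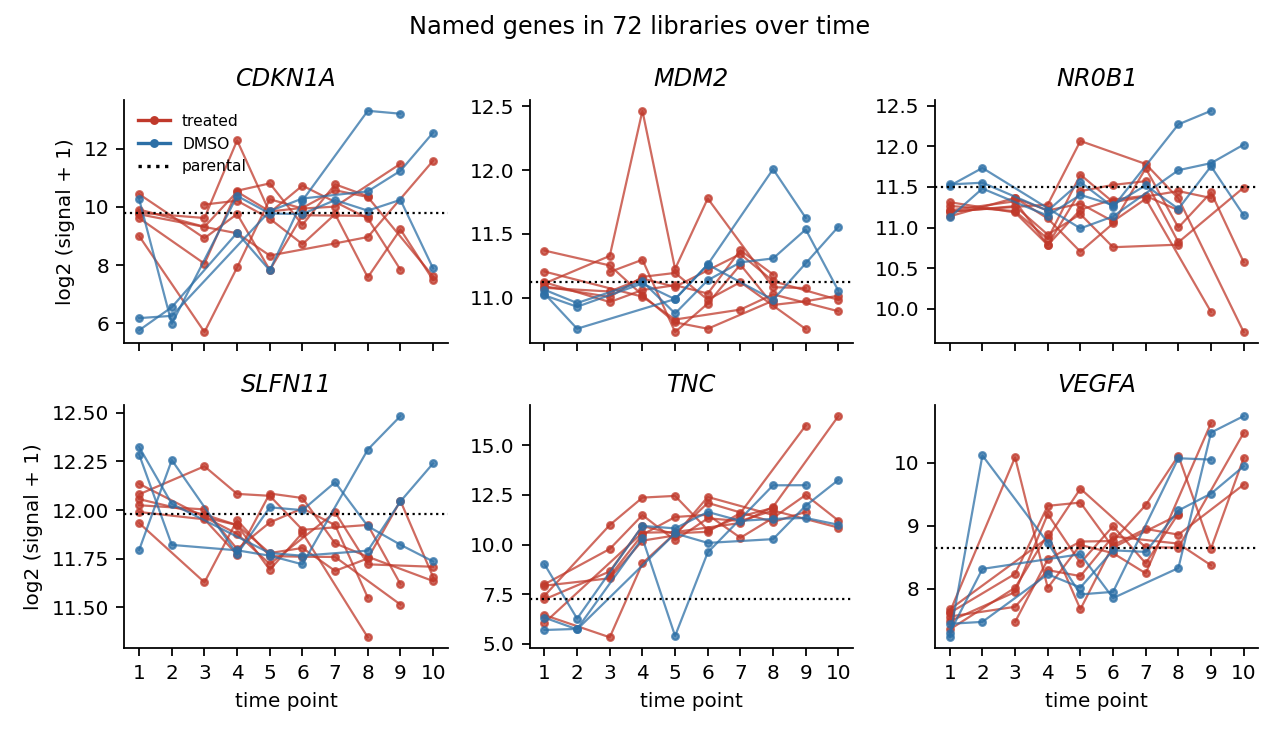
log2 of the normalized count plus 1 (y axes) of 6 genes at each time point (x axes). Points are libraries, lines are lineages (treated red, DMSO blue) and the dotted line is the parental library. TNC and VEGFA were chosen for the plot after their values were seen.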

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

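In this part the tests of depth, normalization, time point 1, drug exposure, cell mixture, blood cells, exchange and labels were chosen only after the result was seen, and so were the splits of comparisons without a call. The permuted time orders and the splits at time point 9 were planned.

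Lone libraries or lineages stood apart from their group in 7 of 82 groups tested, where chance alone would flag about 4.1. That number is a rough guide, since several measures came from the same libraries. Groups of 3 or fewer libraries were not tested, which left out all DMSO groups and the treated groups of time points 9 and 10. Gene and list values were tested in treated lineages only. R1 at time point 3 lay 0.958 from the parental library against 0.707 to 0.786 in the 5 other treated libraries of that time point, and its median correlation with other libraries was 0.928. R1 at time point 6 lay 0.629 from the parental library against at least 0.811 in the others. R7 at time point 4 had 15576 genes at the lowest value against at most 14516. R7 at time point 6 had a ratio of 0.570 between genes at its 2 lowest levels above the floor, against at least 1.04. The time-adjusted MDM2 level of R4 was 11.42 against at most 11.09 in the other treated lineages. G2/M and mitosis genes had a median slope of -0.0762 in R5 against 0.0099 to 0.0467 in the others. R5 was the only treated lineage without a library at time point 1, so its slope covered time points 3 to 10.

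Late DMSO libraries of R9 and R10 held genes at levels far above the other libraries. These genes were chosen by level, so their low values elsewhere follow from the choice. The 47 genes with at least 100 in R9 at time points 8 and 9 and at least 8 times the highest of the other libraries outside late R10 included NPR3, CTNND2, FEV, ETV1, ETV4, LEF1 and VAV1. In R10 at time point 9 these genes lay at a median of 32.2% of their R9 level, and at time point 10 at 70.9%. In R10 at time point 8 the median was 1.90% and in R9 at time point 6 it was 1.49%. Some were seen elsewhere: NPR3 had 122 in R9 at time point 6, and RUBCNL 252 in R1 at time point 9 and 256 in R2 at time point 10. Blood cells are argued against: the 20 blood cell markers had a median value of 2.12 in R9 at time point 9. Depth is unknown, so lower depth cannot be judged directly. By the number of genes at the lowest value the 4 libraries did not stand apart. They had 14266 to 15513, against a median of 14836 and a highest of 16107 over all libraries. Exchange with a treated library cannot be judged by correlation. The highest correlation with one was 0.919 for R9 at time point 8 or 9. For R10 at time point 9 or 10 it was 0.966. All other libraries reached at least 0.978 with their nearest library. The 4 late DMSO libraries fell short of that with any library, reaching 0.972 in R9 and 0.977 in R10, each within its own lineage. A second cell population with a growing share stays open and is a candidate explanation: the genes reached nearly 1 common fraction in R10, with an interquartile range of the log2 fraction of at most 0.602. Whether such cells may be a clone of CHLA-9 or come from another line was not tested. No biological explanation from the design was tested.

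Time slopes were shared by both arms, with r = 0.751 across genes, which argues against drug exposure as the whole cause. Depth is argued against as far as the number of genes at the lowest value tracks it. With that number as a covariate, 4898 genes passed in treated and 1160 in DMSO lineages. A common quantile normalization gave 5727 genes in treated lineages but decides nothing about separate normalization of the arms: above a value of 100 the median sorted columns of the arms differed by at most 0.266%, less than sorted columns within an arm (up to 3.80% in treated and 1.15% in DMSO and parental columns), and a shift between arms leaves slopes within an arm in place. Without time point 1, r across genes was 0.635, yet the counts fell to 426 in treated and 0 in DMSO lineages. That r argues against a step directly after time point 1 as the whole cause of the shared slopes. A step between later time points in both arms would remain without time point 1, so that r cannot judge it. Of 100 time orders, permuted alike in all lineages, 1, the real one, gave as many genes in treated lineages (5741, highest other 4494), and chance order can be excluded there. In DMSO lineages 9 of 100 gave as many as 1437 (highest other 4261), and chance order cannot be excluded. Culture time, which passed in both arms, may be a source of the slopes and stays open. Library batches by time are not labelled, and were not tested.

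R8 at time point 1 and R1 at time point 3 resembled the other arm. R8 at time point 1 correlated at 0.992 with treated libraries of time point 1 and R1 at time point 3 at 0.987 with DMSO libraries of time point 2. An exchange of these with each other cannot be judged. For 1 of the 2 the group it would need fell short of the best correlation by 0.0138. The mean of each group needed held the other of the 2 libraries, which could lower that correlation. Depth is unknown, and by the number of genes at the lowest value R8 at time point 1 did not stand apart (15476, within the range of the others). A wrong arm label of single libraries cannot be told apart from a like state of the cells: the gap was at least 0.0177, but both libraries were picked for it, and 13 libraries lay closer to the other arm. Lineages R8 and R1 exchanged throughout cannot be told apart either, since 11 of their libraries lay closer to the other arm and the rest did not. The libraries were kept in their labelled groups. No biological explanation was tested.

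Other splits of the lineages were counted beside each comparison. Where the real split gave 0 genes in limma, each split gave at least as many by construction, and that count decides nothing. It was 100 of 100 over all time points (highest other 2549 genes), 84 of 84 at time point 1 (40), 100 of 100 at time point 5 (1067), 84 of 84 at time point 6 (227) and 84 of 84 at time point 8 (58). For the slope difference it was 100 of 100 (328), for the last course over splits of the time points 100 of 100 (2500) and for its difference between arms 100 of 100 (23). Genes at an unadjusted p under 0.05 were therefore counted too. As many as the real 1968 over all time points were reached by 5 of 100 splits (highest other 4922). At time point 1, 17 of 84 reached 376 (1981), at time point 5, 75 of 100 reached 197 (3696), at time point 6, 27 of 84 reached 568 (2950), and at time point 8, 11 of 84 reached 1475 (2684). For the slope difference 18 of 100 reached 1332 (3417), for the last course 23 of 100 reached 2118 (4681) and for its difference between arms 42 of 100 reached 685 (2730). None of these shares lies under 0.05, so by these unadjusted counts chance cannot be excluded. At time point 9, 4 of 10 splits gave as many as 194 genes (highest other 1583), and 10 splits are too few for a share under 0.05. Splits calling several times the real count, as here, point to a structure of the samples, which was not tested further.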

How the results depend on the processing

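Every alternative was fitted, and 9 groups of alternatives were chosen after seeing the data: those leaving out named libraries, time points 1 to 7 only, and the covariate. For counts, list counts and distances, 349 alternatives stayed within 1.5 times or on the same side of the threshold, 88 moved and 5 reversed. For named genes 7285 stayed, 385 lost and 228 gained a call, and 141 reversed. For lists 844 stayed, 114 lost and 68 gained a call, and 14 reversed. Where no call or direction held, the cause was not tested. With limma camera at an estimated correlation, 0 lists passed in each of the 5 comparisons. With a pseudocount of 0.1, the counts were 1 (time point 6), 14 (time point 10) and 1 (last course). With a pseudocount of 10, the count was 1 (over all time points). Without a filter on low values, the counts were 4 (time point 1), 100 (time point 4), 10 (time point 5), 14 (time point 6), 23 (time point 8), 131 (time point 10) and 254 (DMSO slopes). With a mean of at least 50, the count was 3 (last course). After another quantile normalization, the count was 6 (last course). Without a trend in limma, the counts were 5 (time point 10) and 5 (last course). With robust limma settings, the counts were 787 (DMSO slopes) and 1 (last course). With duplicateCorrelation on 72 libraries, the count was 19 (over all time points). In a separate fit per time point, the counts were 0 (time point 9) and 0 (time point 10). With array weights, the counts were 5262 (time point 1), 116 (time point 4), 3809 (time point 6), 0 (time point 9) and 0 (time point 10). In a one-stage fit with a replicate block, the counts were 5808 (DMSO slopes) and 321 (slope difference). In a one-stage fit with no replicate block, the counts were 5579 (DMSO slopes) and 83 (slope difference). Without time point 1, the counts were 426 (treated slopes) and 0 (DMSO slopes). Without a replicate block, the count was 41 (last course). With quadratic time and a replicate block, the count was 6 (last course). Without 4 late DMSO libraries, the counts were 0 (time point 9), 0 (time point 10) and 14 (lists over all time points). Without 2 late treated libraries, the counts were 30 (time point 9), 4 (time point 10) and 50 (last course). Without 6 late libraries, the counts were 0 (time point 9), 1 (time point 10), 2717 (DMSO slopes) and 50 (last course). Without R8 time 1 and R1 time 3, the counts were 20 (time point 1) and 11 (last course). Without R7 time 6, the count was 41 (last course). Without 9 libraries, the counts were 292 (time point 1), 0 (time point 9), 0 (time point 10), 2772 (DMSO slopes) and 317 (last course). With time points 1 to 7 only, the counts were 3803 (DMSO slopes) and 39 (last course). The array weights fit stopped before full convergence.

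Leaving out each lineage in turn, counts ranged from 0 to 1357 (over all time points), from 0 to 519 (time point 8), from 0 to 1325 (time point 9), from 0 to 861 (time point 10), from 0 to 2539 (DMSO slopes), from 0 to 158 (slope difference) and from 0 to 164 (last course). The highest counts came without R8, except for the last course, where it came without R1. Signs turned within ranges of -0.0076 to 0.12 for CYTB (over all time points), of -0.0027 to 0.10 for TOP2A (over all time points), of -0.059 to 0.062 for MKI67 (over all time points), of -0.070 to 0.068 for CDKN1A (treated slopes), of -0.015 to 0.015 for SLFN11 (DMSO slopes), of -0.012 to 0.11 for MKI67 (DMSO slopes), of -0.11 to 0.00057 for RRM1 (slope difference), of -0.0080 to 0.00075 for FLI1 (slope difference), of -0.077 to 0.17 for CD79A (last course), of -0.0064 to 0.039 for FLI1 (last course), of -0.53 to 0.16 for CDKN1A (last course) and of -0.14 to 0.00050 for MDM2 (last course).

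Most reversals came when late DMSO libraries were left out or time points 1 to 7 alone were used. Values are log2 differences, and means for lists. With plain lineage means, the sign reversed for ND1 (-0.050), CYTB (-0.089), FLI1 (0.0018) and CDKN1A (0.079) over all time points. With time points 1, 5, 6, 8 and 9, the sign reversed for CYTB (-0.0091) and MKI67 (-0.063) over all time points. With time points 1 to 5, the sign reversed for ITGB2 (0.095), MRE11 (-0.0080), OGG1 (0.0027), H2BC5 (0.0014), CXCL8 (0.27), KRT17 (0.52), CORO1A (0.075), COL3A1 (-0.037), CDKN1A (1.11) and MDM2 (0.11) over all time points. With time points 6 to 10, the sign reversed for CYTB (-0.019), EWSR1 (-0.0097), TOP2A (-0.081) and MKI67 (-0.088) over all time points. In a one-stage fit with no replicate block, the sign reversed for CDKN1A (-0.012) in treated slopes, for SLFN11 (-0.00093) in DMSO slopes. Without time point 1, the sign reversed for MKI67 (0.00088) in treated slopes. In a two-stage fit per lineage, the sign reversed for SLFN11 (-0.00079) for the last course. Without 4 late DMSO libraries, the sign reversed for CXCL8 (0.19), ND1 (-0.019), CYTB (-0.037), CORO1A (0.034), CDKN1A (0.50) and the ATF4 and unfolded protein response genes (0.14) over all time points, for SLFN11 (-0.060) and NR0B1 (-0.017) in DMSO slopes, for PRKCB (0.0076), NKX2-2 (0.17), ABCB10 (0.022), ABCC4 (-0.023), STMN1 (-0.046), NGFR (0.015), TAP2 (0.0066), CXCL8 (0.032), SESN2 (0.055), PFKFB3 (-0.0093), PAX7 (0.11), SLFN11 (0.013) and the ATF4 and unfolded protein response genes (0.046) in the slope difference, for the distance from the parental library (0.0659), for the distance between lineages at the same time point (0.00321). Without 2 late treated libraries, the sign reversed for CDKN1A (-0.037) and NR0B1 (0.0052) in treated slopes. Without 6 late libraries, the sign reversed for ABCA3 (-0.021), CXCL8 (0.22), CDKN1A (0.35) and the ATF4 and unfolded protein response genes (0.11) over all time points, for CDKN1A (-0.037) and NR0B1 (0.0052) in treated slopes, for SLFN11 (-0.060) and NR0B1 (-0.017) in DMSO slopes, for PRKCB (0.0057), NKX2-2 (0.16), COL1A2 (-0.013), ABCB10 (0.013), ABCC4 (-0.028), STMN1 (-0.038), NGFR (0.036), USP18 (0.00083), TAP2 (0.021), TAPBP (0.0018), CXCL8 (0.084), PFKFB3 (-0.016), CD79A (0.021), PAX7 (0.11), SLFN11 (0.016), NR0B1 (0.022), the topoisomerases and tubulins (-0.040) and the ATF4 and unfolded protein response genes (0.020) in the slope difference, for the distance from the parental library (0.0388). Without R8 time 1 and R1 time 3, the sign reversed for CDKN1A (-0.012) in treated slopes, for SLFN11 (-0.0039) in DMSO slopes. Without 9 libraries, the sign reversed for ABCA3 (-0.066), CXCL8 (0.25), CDKN1A (0.44) and the ATF4 and unfolded protein response genes (0.11) over all time points, for CDKN1A (-0.060) and NR0B1 (0.0061) in treated slopes, for SLFN11 (-0.068) and NR0B1 (-0.022) in DMSO slopes, for PRKCB (0.0084), NKX2-2 (0.17), COL1A2 (-0.022), ABCB10 (0.018), ABCC4 (-0.024), STMN1 (-0.039), NGFR (0.035), USP18 (0.0031), TAP2 (0.023), CXCL8 (0.11), PFKFB3 (-0.0094), CD79A (0.024), PAX7 (0.12), SLFN11 (0.021), NR0B1 (0.028), the topoisomerases and tubulins (-0.044) and the ATF4 and unfolded protein response genes (0.022) in the slope difference, for the distance from the parental library (0.026). With time points 1 to 7 only, the sign reversed for CXCL8 (0.47), COL3A1 (-0.026), FLI1 (0.00090), CDKN1A (0.66), MDM2 (0.040), the G1/S and replication genes (-0.0021) and the ATF4 and unfolded protein response genes (0.15) over all time points, for NR0B1 (0.036) in treated slopes, for SLFN11 (-0.058) and NR0B1 (-0.045) in DMSO slopes, for CBX6 (0.0039), GPR37L1 (0.035), PRKCB (0.021), NKX2-2 (0.23), COL1A2 (-0.024), ABCB10 (0.019), ABCC4 (-0.036), STMN1 (-0.087), NGFR (0.080), IFITM2 (0.021), TAP2 (0.062), TAPBP (0.040), ICAM1 (0.095), CXCL8 (0.26), SESN2 (0.012), PFKFB3 (-0.0030), CD79A (0.048), PAX7 (0.17), SLFN11 (0.026), FLI1 (0.0037), NR0B1 (0.081), the EWSR1-FLI1-activated genes (0.0045), the topoisomerases and tubulins (-0.067), the mesenchymal and extracellular matrix genes (-0.017) and the ATF4 and unfolded protein response genes (0.034) in the slope difference, for CD79A (-0.059) and SLFN11 (-0.0039) for the last course, for the distance from the parental library (0.0337). With the genes at the lowest value as a covariate, the sign reversed for CDKN1A (-0.037) in treated slopes.

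Depth is unknown from normalized values, and no limit from depth was computed.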

Other observations

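Late treated libraries also held genes far above the other libraries. The 44 genes with at least 100 in R1 at time point 9 and R2 at time point 10, and at least 8 times the highest of the other libraries, included KRT34, ADAM19, TGFB2, FGF5 and HGF. In R1 at time point 7 they lay at a median of 2.94% of that level, and in R7 at time point 5 at 2.71%. These genes were chosen after their values were seen.

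The correlation across genes of treated and DMSO slopes was 0.695 without 9 libraries and 0.786 over time points 1 to 7. R8 had 7 of its 9 libraries closer to a treated group than to a DMSO group, R1 had 4 of 7 closer to a DMSO group, and the lineages R2, R3, R4, R5, R6 and R10 had none.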
